A study of Mus musculus with 6 samples.

How the data were processed

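RNA from the cortex of 8-week-old male mice was measured on 6 single-colour Agilent arrays, 3 from sham-operated mice and 3 from mice killed 12 h after reperfusion that ended a transient occlusion of the middle cerebral artery (tMCAO). Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed, and the remainder was copied by random priming along whole transcripts into Cy3-labelled cRNA. The labels describe 3 independent experiments per group and RNA taken from each mouse, and no further detail on cages, litters or surgery days was used here.

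Each array's scanner table was made with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes, and its values are spot intensity on a linear scale, deposited without normalization between arrays. Per the file headers, the processed signal is background-subtracted. The authors also deposited a table of log2 normalized values for the same 6 arrays, with 60902 probes, of which 60819 matched a probe that could be tested here. Its column medians lay between 6.8914 and 6.8927, and each column correlated with its own array's log2 signal across probes (r of at least 0.99992). The method behind that table is not given in the sources used here, so its centring remains unknown, and it served as an alternative.

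Each array held 62939 spots, of which 61500 were not controls, and 15 negative probes with 300 spots among these were left out. The processed signal was log2-transformed and the array's 75th percentile over the non-control spots was subtracted. Spots with an outlier mark were removed, and spots of one probe were averaged. A probe was tested if it was well above background on at least 3 of the 6 arrays and had at least 2 values per group. Of 60915 probes, 44288 were tested, 16590 were too dim and 37 were lost to outlier marks. tMCAO was compared with sham by limma 3.58.1 (lmFit and eBayes, two-sided, 4 residual degrees of freedom) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Levels are log2 signals relative to the array's 75th percentile, and a level of one probe was not set against that of another. Where a probe was not well above background on any array of a group, the fold is a lower bound, taken against the lowest signal among probes well above background on each array or the probe's own signal, whichever was higher. Files were read with the R package data.table (version 1.17.8) and plots were drawn with matplotlib 3.10.9.

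The design set before the data were examined compared protein-coding with noncoding transcripts and tested 40 gene lists. The tables used pair only 15 probes with a RefSeq accession, each spotted 20 times, and all 15 accessions were given a symbol through a RefSeq table of assembly GRCm38.p6. The other probes carry design codes or names that contain lincRNA (long intergenic noncoding RNA), and no annotation that ties the codes to genes was used here. For this reason 38 of the 40 lists had no named member, including every list of stress, inflammatory, neuronal, glial and vascular genes. Of the other 2 lists, the ribosomal protein list had 1 named member, too few for a test that needed 3, and the reference gene list had 8 of its 14 members. Markers of other cell types could therefore not be examined by name. The comparison of coding with noncoding probes was replaced by one of lincRNA-named with design-code probes, whose own class is unknown. No coordinates are given, because the array's design and the RefSeq table use different genome builds. Probe sequences were not used, so hybridization of transcripts from near-identical gene copies, such as those of tubulin, actin and glyceraldehyde-3-phosphate dehydrogenase, was not assessed.

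The naming rule set in advance took genes past the threshold with the largest rises and falls, no overlap between groups and signal well above background on all 3 arrays of the higher group, and 2 bright members of any list with none past it. Because design codes are anonymous, the 2 largest rises and the 2 largest falls by that rule are given by code. They were ranked by fitted log2 change, also where the fold is only a bound and the rank is therefore uncertain. lincRNA-named probes were named by the same rule, and 1 more that passed the threshold was named after its values had been seen. All 15 accession-named genes are reported. The reference gene list was tested with camera (inter-gene correlation preset at 0.01), with an estimated correlation and with fry. Shares of changed probes were compared with Fisher's exact test, two-sided. That test treats probes as independent, so its p-values and intervals do not measure spread between arrays. Single measures per array were compared with exact two-sided permutation tests, whose smallest possible p with 3 arrays against 3 is 0.1.

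On simulated data with the real probes' means and spread, 200 of 44103 probes were given a known change in the comparison of tMCAO with sham. The test recovered 7.5% of 1.5-fold, 55.2% of 2-fold and 87.9% of 4-fold changes, with 7 false calls, and made 0 calls when no probe was changed. The simulation was run once, with noise independent between probes and arrays. Differences that run through a whole array were not simulated, so these values are not error rates for the real arrays. All 6 arrays came from 1 slide and 1 scan, so slide and scan could not act as batches. Both rows of the slide held both groups, but the sides were not balanced. In row 1, tMCAO lay in columns 1 and 2 and sham in columns 3 and 4. In row 2, sham lay in column 1 and tMCAO in column 2. Alternatives covered the background correction, normalization, filters, blocks for replicate number and slide row, variance model, array weights, and leaving out each array in turn. The alternatives with slide row, with normexp on median signals, and with quantile normalization without 1 array were chosen after seeing the data, as were the lists of bright probes and of lincRNA-named probes tested as a class.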

Results

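Gene expression and noncoding RNA were profiled in mouse cortex after sham surgery or 12 h after reperfusion following transient middle cerebral artery occlusion (tMCAO), a model of ischemic stroke. There were 3 arrays per group. The 75th percentile of the processed signal was 555.5, 605.9 and 705.5 intensity units on the sham arrays and 934.6, 918.6 and 537.2 on the tMCAO arrays. Its log2 value was 9.27 ± 0.18 in sham and 9.59 ± 0.45 in tMCAO (SD, n = 3 each; exact permutation p = 0.4, in a test that cannot go below 0.1), and tMCAO replicates 1 and 2 lay above every sham array. Between 70.1% and 73.9% of probes were well above background on each array, and 0 spots were saturated. The difference between 3′ and 5′ control probes, as their names give them, was 0.90 ± 0.09 log2 units in sham and 0.84 ± 0.15 in tMCAO for Gapdh, and 8.01 ± 0.19 and 8.14 ± 0.27 for Pgk1 (SD, n = 3 each; exact permutation p = 0.7 for both). The number of arrays limits the precision of every value below.

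The first comparison asked which transcripts differed in the ischemic cortex. Rises outnumbered falls: 547 of 44288 probes were higher and 83 were lower after tMCAO (limma, adjusted p under 0.05), so that 86.8% of the 630 changed probes were higher. Of these, 286 rose and 20 fell by at least 2-fold, and 54 rose and 1 fell by at least 4-fold. The median rise was 1.03 log2 units (2.05-fold), and the median log2 change of the probes that fell was -0.82 (1.77-fold lower). The excess of rises was present at every signal level. With probes divided by mean signal into 3 equal groups, there were 204 rises and 39 falls among the dimmest, 220 and 25 in the middle group, and 123 and 19 among the brightest. It was absent from the 7930 probes with an unadjusted p under 0.05, of which 3766 were higher and 4164 lower. The groups did not overlap for 10957 probes (24.7%, against 10% by chance), 5150 of them higher and 5807 lower.

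The probe with the largest rise among those that met the naming rule was ASMM10P030639, at -3.55 ± 0.37 in sham and 1.35 ± 0.54 in tMCAO (log2 signal relative to the 75th percentile, SD, n = 3 each). This was a rise of 4.91 ± 0.29 log2 units (SE), or 30.0-fold (limma, adjusted p = 0.000928). ASMM10P011472 was not well above background on any sham array and was at least 3.61-fold higher after tMCAO (limma, adjusted p = 0.00741). The falls named by the rule were those of ASMM10P025794, with a log2 change of -2.24 ± 0.31 (SE; limma, adjusted p = 0.0188), and ASMM10P015034, with -1.83 ± 0.20 (SE; limma, adjusted p = 0.00876). ASMM10P025794 was well above background on only 1 of the 3 tMCAO arrays, so the size of its fall is uncertain. ASMM10P030639 passed without any 1 array, whereas the other 3 missed the threshold without tMCAO replicate 1 (limma, adjusted p = 0.0567, 0.0567 and 0.0599), and ASMM10P025794 also without sham replicate 1 (0.0831) or 2 (0.0655) and with no filter on dim probes (0.0506). With normexp, the log2 changes of the 4 were 3.77, 1.22, -1.002 and -1.21 in the order given, and the second lies under the bound above. That setting changed both the background method, with its offset, and the signal used (medians). Which of them narrowed the changes was not tested. The genes behind these 4 design codes are not named here.

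**Figure D1:**
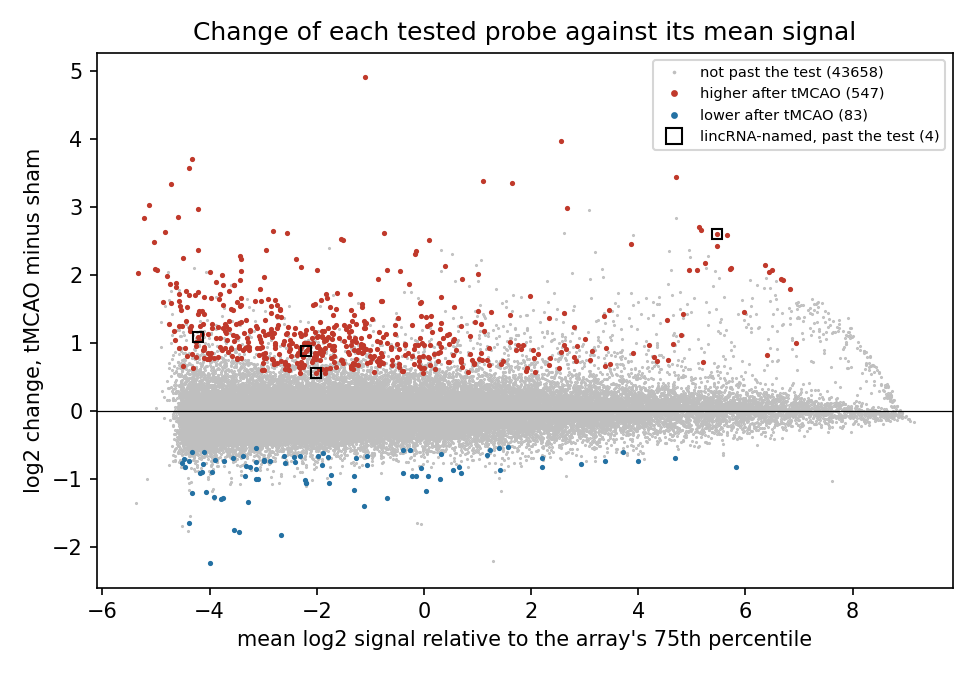
Log2 change after tMCAO (y) against the mean log2 signal relative to the array's 75th percentile (x) for each of the 44288 tested probes. Red points are the 547 probes higher and blue points the 83 lower after tMCAO, grey points did not pass the limma test, and squares mark the 4 changed lincRNA-named probes. A band of bright probes above 0, at a signal of over 4, is mostly grey.

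The counts depended on the processing and on single arrays. With normexp 330 probes were higher and 40 lower, 127 and 6 of them by at least 2-fold, and with no filter on dim probes 244 were higher and 19 lower. With signal above background on all 6 arrays, 190 rose and 12 fell by at least 2-fold, and with a trended robust variance 158 probes were lower. With replicate number as a block, 353 probes were higher and 35 lower. The numbers higher and lower were 112 and 7 without sham replicate 1, 209 and 15 without sham replicate 2, and 145 and 12 without sham replicate 3. They were 96 and 5 without tMCAO replicate 1, 356 and 43 without tMCAO replicate 2, and 778 and 284 without tMCAO replicate 3. Rises made up 73.3% of the changed probes without tMCAO replicate 3. In none of these fits did a probe changed over all 6 arrays pass the threshold in the other direction. Because the fits reuse the arrays on which the probes were called, this was nearly fixed in advance.

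Among the 15 genes named on the array, those for the immune and lysosomal proteins B2m and Gusb lay highest relative to sham. B2m, the light chain of class I major histocompatibility molecules, was at 5.38 ± 0.05 in sham and 5.93 ± 0.08 in tMCAO (log2, SD, n = 3 each). The difference was 0.56 ± 0.11 log2 units (SE), or 1.47-fold, without overlap between groups, and lay just outside the threshold over all probes (limma, adjusted p = 0.0529). It passed when adjusted over the 15 named genes (limma, adjusted p = 0.0117). B2m also passed over all probes without tMCAO replicate 3 (limma, adjusted p = 0.0469), with array weights (0.0422) and with a trended robust variance (0.0131). Over all alternatives its adjusted p ranged from 0.0131 to 0.19. Gusb, the lysosomal enzyme beta-glucuronidase, differed by 0.46 ± 0.12 log2 units (SE), without overlap between groups (limma, adjusted p = 0.131 over all probes and 0.0431 over the 15). The groups also did not overlap for Tfrc (higher) and Tuba1b (lower), both described below. Lack of overlap thus held for 4 of the 15 genes (26.7%), near the share of 24.7% over all tested probes.

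Transferrin receptor Tfrc, which takes up iron-bound transferrin, differed by 0.28 ± 0.13 log2 units (SE) and the TATA-binding protein gene Tbp by 0.23 ± 0.14, and neither passed the test (limma, adjusted p = 0.317 and 0.401). The chaperone gene Hsp90ab1 differed by 0.16 ± 0.13 (SE; limma, adjusted p = 0.528), and the glycerol kinase gene Gk by 0.08 ± 0.14 with 2 tMCAO values (SE; limma, adjusted p = 0.786). In the authors' table, which keeps the value of tMCAO replicate 2, the difference of Gk was 1.01 log2 units (limma, adjusted p = 0.334, within 0.334 to 0.963 over all alternatives). Below sham lay the cytoskeletal genes Tuba1b, at -0.21 ± 0.12, and Actb, at -0.16 ± 0.17 (SE; limma, adjusted p = 0.397 and 0.623). The testis-type lactate dehydrogenase gene Ldhal6b lay at -0.20, the ribosomal protein gene Rpl13a at -0.11, the cyclophilin gene Ppia at -0.11, the purine salvage gene Hprt at -0.09 and the glycolytic gene Gapdh at -0.09 log2 units, with limma adjusted p between 0.478 and 0.7. The RNA-binding protein gene Nono, at -0.03, and G6pd2, at -0.0047 log2 units, were above 0 under other scalings (0.0017 for Nono with median centring and 0.0119 to 0.0232 for G6pd2).

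In the list of reference genes, 8 of 14 members were measured, namely Actb, Gapdh, Hprt, Tbp, Ppia, B2m, Gusb and Tfrc. Of these, 0 passed limma's test over all probes, while 2 of the 8 had an unadjusted p under 0.05. When adjusted over the list alone, 2 were higher, B2m and Gusb, and 0 were lower. The list's median was 0.07 and its mean 0.13 log2 units, with 4 members above and 4 below 0, and its median turned to -0.0367 with quantile normalization and to -0.0634 in the authors' table. The list did not stand apart from other probes in camera (p = 0.0756, and p = 0.14 with an estimated correlation), whereas fry gave p = 0.0122 for a shift of its members to 1 side and p = 0.00167 for change in either direction. The fry test asks whether the members changed at all, not whether they changed more than other probes. It therefore answers a different question from camera. The list passed limma's camera without tMCAO replicate 1 (median 0.048, adjusted p = 0.0377), with normexp (median 0.0837, adjusted p = 0.00865) and with no filter on dim probes (median 0.0686, adjusted p = 0.0391).

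**Figure D2:**
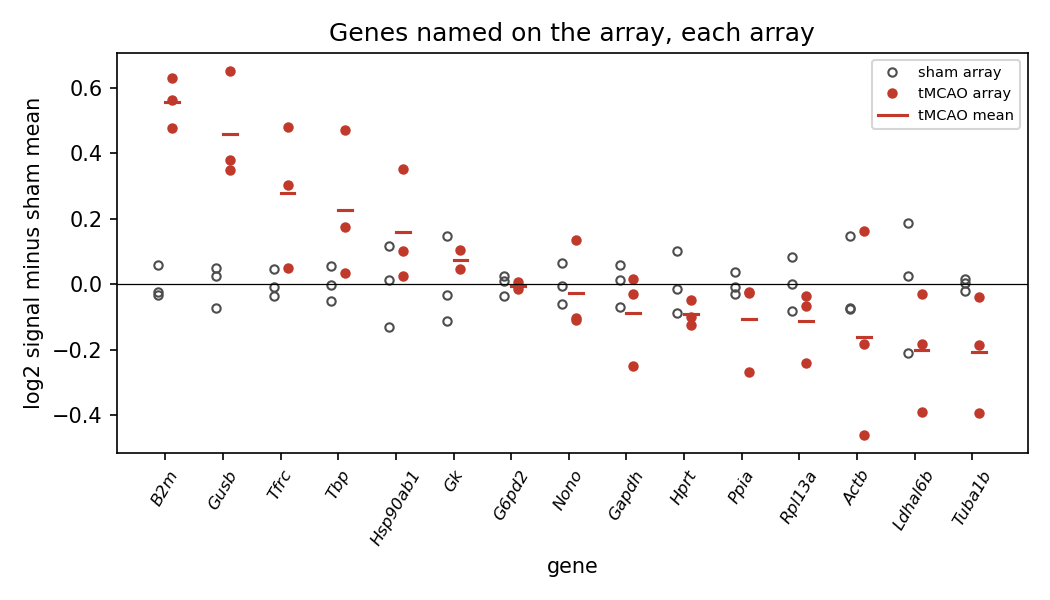
Log2 signal of the 15 accession-named genes (x) on each array, minus the gene's sham mean (y). Open points are sham arrays, filled points tMCAO arrays and short lines the tMCAO mean, with 3 arrays per group except for Gk, which has 2 tMCAO values. B2m, Gusb and Tfrc lie above every sham value of the gene, at means of 0.56, 0.46 and 0.28. Tuba1b lies below every sham value, at a mean of -0.21.

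The second comparison concerned noncoding transcripts, for which the probes with lincRNA in their names were used. Only 630 of 1836 such probes (34.3%) had enough signal to be tested, against 73.9% of design-code probes. After tMCAO 4 rose and 0 fell (limma), while at an unadjusted p under 0.05 the numbers were 19 higher and 119 lower. humanlincRNA1516-_P1 rose by 2.60 ± 0.22 log2 units (SE), or 6.05-fold, with 2 arrays per group after outlier removal (limma, adjusted p = 0.00951). With the removed spots kept, it lay at 3.32, 4.26 and 4.09 on the sham arrays and at 7.05, 6.49 and 5.58 on the tMCAO arrays. It was thus higher in sham replicate 2 than in sham replicate 1 and rose least on tMCAO replicate 3. The group of 255 bright probes described below has the same pattern. It includes 4 lincRNA-named probes, but none of the 4 that rose. The group took only bright probes with a value on every array, which humanlincRNA1516-_P1 lacks after outlier removal. The others that rose were too dim in sham. MM9LINCRNAEXON11561-_P1 was not well above background in sham and was at least 1.56-fold higher after tMCAO (limma, adjusted p = 0.0128). mouselincRNA1177-_P1 rose by 0.88 ± 0.16 and MM9LINCRNAEXON11569-_P1 by 0.56 ± 0.10 log2 units (SE; limma, adjusted p = 0.0452 for both). These last probes lost their calls under 11 and 10 of 16 alternatives, with adjusted p up to 0.161 and 0.208. Among fits without 1 array, humanlincRNA1516-_P1 missed the threshold without sham replicate 3 or tMCAO replicate 1 (limma, adjusted p = 0.0618 and 0.0517), and MM9LINCRNAEXON11561-_P1 without sham replicate 1 or tMCAO replicate 1 (limma, adjusted p = 0.0612 and 0.075). With normexp the log2 changes were 0.27 for MM9LINCRNAEXON11561-_P1, which lies under the bound above (limma, adjusted p = 0.368), 0.53 for mouselincRNA1177-_P1 (0.114) and 0.36 for MM9LINCRNAEXON11569-_P1 (0.208).

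Changed probes made up 0.635% of the lincRNA-named probes (4 of 630) and 1.43% of the design-code probes (626 of 43643). The difference in shares did not pass the test (odds ratio 0.439, 95% interval 0.119 to 1.14, Fisher's exact test, p = 0.123). It did with a trended robust variance (odds ratio 0.443, Fisher's exact test, p = 0.036) and with replicate number as a block (odds ratio 0.178, Fisher's exact test, p = 0.0493). In the dimmest of the 3 signal groups, 1 of 398 lincRNA-named and 242 of 14365 design-code probes had changed (odds ratio 0.147; Fisher's exact test, p = 0.016). In the middle and brightest groups the odds ratios were 0.738 (p = 1) and 1.49 (p = 0.493; both Fisher's exact test). Fisher's exact test treats probes as independent, whereas the lincRNA-named probes were correlated. The estimated correlation within the class was 0.12 with quantile normalization and 0.61 with normexp. The p-values and the interval therefore do not measure spread between arrays, and they do not decide whether the shares differ. Without tMCAO replicate 3 the odds ratio was 1.34, with 16 lincRNA-named probes lower. The class pools 3 kinds of name. Changed were 1 of 358 humanlincRNA probes (0.279%), 1 of 231 mouselincRNA probes (0.433%) and 2 of 41 MM9LINCRNAEXON probes (4.88%). The last share lay above that of the design-code probes.

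The lincRNA-named probes lay slightly below sham as a class on tMCAO replicates 1 and 2, but near sham on replicate 3. Their median log2 change was -0.24, with 529 of 630 (84%) below 0, and it was -0.17 with quantile normalization, -0.21 with median centring and -0.24 with normexp background correction. Random lists of design-code probes of the same mean signal had a median of -0.09, and in the other scalings of -0.04, -0.06 and -0.15 in the same order, so the gap was smallest with normexp. In each of these scalings 0 of 10000 such lists lay as low as the class. Such lists treat probes as independent, whereas the estimated correlation within the class was 0.12 to 0.61 over the scalings. The class passed camera with the preset correlation (p = 9e-08) but not with an estimated one (p = 0.367). In the other scalings camera with an estimated correlation gave p = 0.248, 0.222 and 0.456 in the same order. The median was -0.32 and -0.37 on tMCAO replicates 1 and 2 and 0.01 on tMCAO replicate 3, relative to the sham mean. tMCAO replicates 1 and 2 also had the highest 75th percentiles (934.6 and 918.6) and replicate 3 the lowest (537.2). The shift was therefore not separated from array brightness. Of 876 lincRNA loci with probes for both strands, as read from the probe names, 115 were tested on both, 181 on the plus strand alone and 188 on the minus strand alone. Across those 115 loci the changes on the plus and minus strands were unrelated (r = -0.0053, Spearman's rho 0.0697, permutation p = 0.951 for r), and loci are not independent replicates.

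Some transcripts were detected in 1 group alone. There were 195 probes well above background on all 3 tMCAO arrays and no sham array, 65 of them changed by the limma test, and 14 probes with the reverse pattern, 4 of them changed. Detection also followed the arrays themselves, because a split of sham replicates 1 and 3 and tMCAO replicate 3 from the other 3 arrays gave 325 such probes, against 213 for the real split when counted over all probes.

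A group of bright probes differed between the sham arrays and was higher after tMCAO. Of 3813 probes with a mean sham signal over 4 log2 units above the 75th percentile, 255 were more than 0.5 log2 units higher in sham replicate 2 than in sham replicate 1, while 17 were lower by that much. These 255, chosen without the tMCAO arrays, had a median log2 change after tMCAO of 1.09 (2.12-fold), and 242 of them (94.9%) were above 0. Only 10 of the 255 passed the limma test, yet they include 139 of the 698 probes whose means differed upward by at least 2-fold. Relative to the sham mean, their median was -0.51, 0.52 and -0.01 on sham replicates 1, 2 and 3 and 1.20, 1.42 and 0.56 on tMCAO replicates 1, 2 and 3. For 255 other bright probes of the same sham signal the median change was 0.0064.

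**Figure D3:**
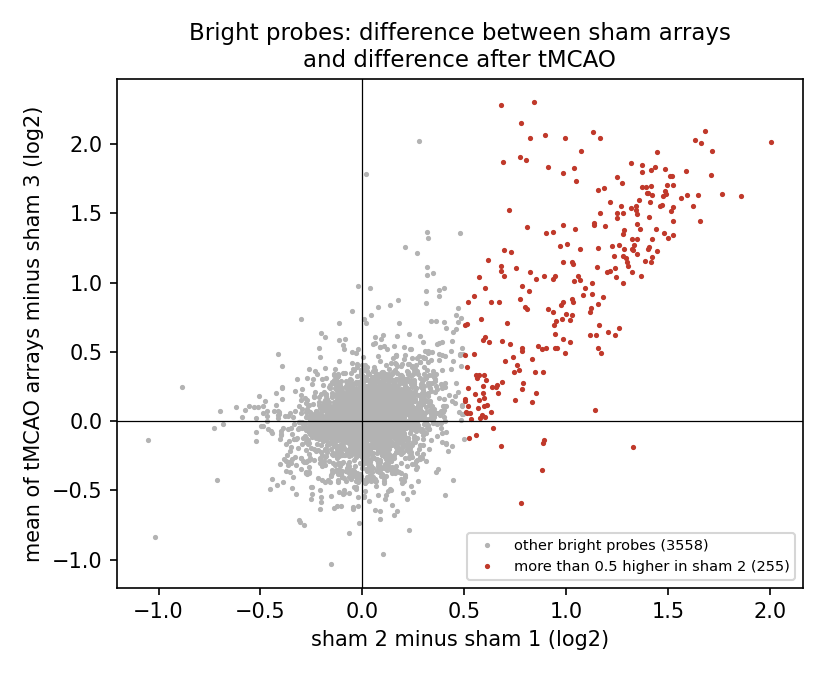
Difference between the tMCAO mean and sham replicate 3 (y, log2) against the difference between sham replicates 2 and 1 (x, log2) for 3813 bright probes. No array enters both axes. Red points are the 255 probes more than 0.5 higher in sham replicate 2, most of which lie above 0 on the y axis, and grey points are the others.

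The groups lay apart on the first principal component, which held 47.9% of the variance, but tMCAO replicate 3 lay between the other tMCAO arrays and sham. Its score was -3.2, against 44.6 and 55.9 for tMCAO replicates 1 and 2 and -37.1, -23.1 and -37.0 for the sham arrays (exact permutation p = 0.1, the smallest possible). Across probes, tMCAO replicate 3 correlated at 0.9925 with each sham array, and at 0.9922 and 0.9906 with tMCAO replicates 1 and 2. Sham arrays correlated with each other at 0.9945 to 0.9954. The median SD between replicates was 0.13 log2 units in sham and 0.18 in tMCAO, and 66.0% of probes had the larger SD in tMCAO.

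**Figure D4:**
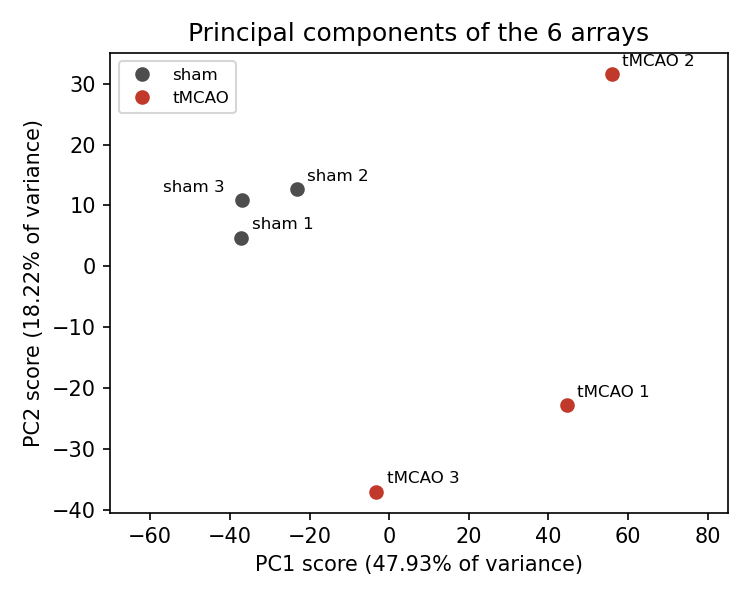
Scores of the 6 arrays on the first (x, 47.9% of variance) and second (y, 18.2%) principal components of the tested probes. Each point is 1 array, grey for sham and red for tMCAO. The sham arrays lie together at -37.1 to -23.1 on the first component, and tMCAO replicate 3 lies at -3.2.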

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

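No probe changed by the chosen test lay in the other direction under an alternative that tested it. The alternatives reuse the same arrays, so this is no separate support for a direction. B2m, Gusb and the 4 design-code probes kept their direction under each alternative that changed 1 choice and tested them. With normexp (on medians, chosen after seeing the data) 330 probes were higher and 40 lower, 127 and 6 by at least 2-fold, and 1 lincRNA-named probe was higher. With no filter on dim probes, where more probes enter the adjustment, 244 were higher and 19 lower, 12 fell at least 2-fold, and 2 lincRNA-named probes were higher and 1 lower. The reference list passed limma's camera in both settings, at a median of 0.0837 with normexp (adjusted p = 0.00865) and 0.0686 with no filter (adjusted p = 0.0391); with 1 list tested, adjustment over lists leaves p as it is. With signal above background on all 6 arrays, and so fewer probes, 190 rose and 12 fell at least 2-fold and 2 lincRNA-named probes rose. Trended robust variance gave 158 lower, 1 accession-named gene changed (B2m) and an odds ratio of 0.443 (Fisher's exact test, p = 0.036), and array weights gave 1 such gene (B2m); tMCAO replicate 3 had the lowest weight, 0.511. The reference list's median turned to -0.0367 with quantile normalization and -0.0634 in the authors' table, and fry passed at a median of 0.0686 (p = 0.0122). The odds ratio was 0.147 among the dimmest and 1.49 among the brightest probes when these were divided by signal into 3 equal groups. G6pd2 turned to 0.0119 with quantile normalization, 0.0232 with median centring and 0.0183 in the authors' table, and Nono to 0.0017 with median centring. Quantile normalization without tMCAO replicate 3, chosen after seeing the data, gave 925 higher and 191 lower, 562 and 36 by at least 2-fold. Except where noted, the cause was not tested.

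Leaving out 1 array at a time gave 96 to 778 probes higher and 5 to 284 lower, 90 to 484 and 4 to 43 by at least 2-fold, 0 to 4 lincRNA-named probes higher and 0 to 16 lower, and 0 to 1 accession-named genes changed. The odds ratio ranged from 0 to 1.34, the reference list's median from 0.032 to 0.107, G6pd2 from -0.0224 to 0.008 and Nono from -0.106 to 0.015. With the replicate number as a block, 353 probes were higher and 35 lower, 1 lincRNA-named probe was higher (humanlincRNA1516-_P1, mouselincRNA1177-_P1 and MM9LINCRNAEXON11569-_P1 lost their calls, at limma adjusted p = 0.0532, 0.0804 and 0.104) and the odds ratio was 0.178 (Fisher's exact test, p = 0.0493). Same-numbered arrays correlated in their deviations at 0.021, 0.095 and 0.127, and sham replicates 1 and 2 correlated best with another number, so the numbers were not taken as pairs. Normexp on mean signals, slide or scan as a block and means over several probes of a gene were not run, because the column was not used here, there was 1 slide and 1 scan, and each named gene had 1 probe. The variance and weight settings were not applied to camera. Signal over background allowed 34.3% of the lincRNA-named probes to be tested.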

Other observations

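The tests of sham RNA on tMCAO replicate 3, of scaling as the source of the excess of rises and of scaling of bright probes were chosen after those results had been seen, as were the choice of the bright probes and the test of neighbouring codes.

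Rises after tMCAO were clustered along the design codes. Of 33318 pairs of tested probes with consecutive codes, 27 pairs had both probes higher, against a mean of 5.2 and a maximum of 16 in 10000 random orders (permutation p = 1e-04, the smallest they can give). In all, 51 of the 541 higher probes with such codes had a higher neighbour, and spots of these pairs lay 0.806 times as far apart as spots of random pairs of higher probes.

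The bright probes that varied between sham arrays are the first pattern to follow up, since they carry 139 of the 698 upward differences of at least 2-fold and could be read as a response to ischemia. Scaling of bright probes between arrays is argued against by the matched bright probes, whose median change was 0.0064 log2 units, and by quantile normalization, under which the chosen probes still had a median of 0.96. A patch on the array is argued against by the distance from a chosen spot to the nearest other, 1.08 times that in random sets of bright spots. Over the tMCAO arrays, which took no part in the choice, 92.6% of the variance of the chosen probes lay on 1 component, against 62.2% for the matched probes, so 1 common factor may move them together. What that factor is stays open: a class of abundant RNA left in differing amounts by the removal of ribosomal RNA and a true rise after tMCAO were not tested, and the probes' targets are not named here.

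Falls after tMCAO were small on tMCAO replicate 3. With 1 array of each group held out, 500 probes were chosen from the other 4 arrays, and 46 to 105 of the 500 were falls. The held-out fall was on average 0.586 of the chosen fall on tMCAO replicate 1, 0.538 on replicate 2 and 0.172 on replicate 3. Sham RNA on tMCAO replicate 3 is argued against by the held-out rises, which averaged 0.886 log2 units there. These too were the weakest, at 0.65 of the chosen rise against 1.06 and 0.837 on tMCAO replicates 1 and 2. Over all tested probes that array correlated slightly better with each sham array (r = 0.9925) than with tMCAO replicates 1 and 2 (0.9922 and 0.9906). Scaling may account for part of it, because with quantile normalization the share for tMCAO replicate 3 rose to 0.384 (0.223 to 0.575 over the sham arrays), while that of tMCAO replicate 2 dropped to 0.353 and that of tMCAO replicate 1 was 0.635. All tMCAO arrays and sham replicate 3 lay on the left of the slide. An effect of place would give tMCAO replicate 3 larger falls against sham replicates 1 and 2, on the right, than against sham replicate 3. The shares were 0.271 and 0.0336 against 0.211, 1 larger and 1 smaller, so they do not decide it. Place cannot be told apart as a partial source, since these shares are few. Over 100 probes that fell in the first row, sham replicate 3 lay at 0.244 and tMCAO replicate 3 at 0.486 of the way from sham to tMCAO (95% intervals 0.181 to 0.374 and 0.348 to 0.611). Over 400 probes that rose in the first row, these arrays lay at 0.014 and 0.766. The intervals come from resampling the probes of 1 array, so they hold no spread between arrays. A milder injury was not tested.

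The excess of rises among changed probes is the last pattern. Scaling is argued against, because the share of rises was at least 86.3% under quantile, median and normexp scaling, and falls lost near the background are argued against by a share of 86.6% among the brightest of 3 equal groups of probes. The small falls on tMCAO replicate 3 cannot be told apart as a partial source, because without that array the share of rises was 73.3%, and 82.9% when quantile normalization was used as well. Among the 7930 probes with an unadjusted limma p under 0.05 there was no excess of rises, with 3766 higher and 4164 lower. An excess of induction over repression 12 h after reperfusion therefore stays a hypothesis.

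The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 630 changed probes, 306 changed at least 2-fold and 4 changed lincRNA-named probes. The highest of the other splits gave 0 for each, so 1 split of the 10 reached the real value in each case. In a split that mixes the groups, their difference adds to the spread within each part, which by itself keeps calls low. The contrast with 0 therefore does not measure how far the groups lie apart.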
